A study of Xenopus laevis with 8 samples.

How the data were processed

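The data came from 8 RNA-sequencing libraries of cultured, wild-type Xenopus laevis ectodermal explants at the early neurula stage, 2 each of control explants and explants expressing Chordin, Flag-tagged Pinhead or both. Per the labels, RNA was purified with RNeasy columns and read as paired ends of 150 bp. The deposited table holds, per the authors, raw counts per gene in 2 columns for each library. The values are whole numbers with different totals per column, which was checked. Reads were aligned with HISAT2 according to the submitters' processing notes, and its version, the counting tool, the genome build and the annotation are not given in the sources used here. The 2 columns of a library were treated as runs of 1 library and summed: their mean chi-square per gene was 1.39 to 1.53 within a library, against 3.19 to 12.8 between the 2 libraries of a group. Of the table, 45035 genes were used and 1 line was not analysed here. Genes kept the symbols of the table, with the long and short copies as separate genes, and no genome coordinates were used.

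The libraries held 15052017 to 19677493 counts, and 1 CPM, the unit of library-scaled counts, stood for 14.5 to 19 counts after scaling. The 10 most abundant genes took 6.68% to 8.88% of a library. All statistics were computed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Counts were scaled by trimmed mean of M values (TMM factors 0.95 to 1.05), genes were kept by filterByExpr with its default minimum of 10 counts and 15 in total, which left 23130, and 1 quasi-likelihood model with a coefficient per group was fitted to the 8 libraries, leaving 4 residual degrees of freedom (common dispersion 0.014). The 7 comparisons were each protein and both against control, both against each protein, Pinhead against Chordin, and the interaction of the 2 proteins. Two-sided p-values were adjusted by Benjamini-Hochberg within a comparison, and genes with an adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Principal components were computed on log2 CPM of the genes tested. The comparisons, the 24 gene lists, the rules for naming genes and the alternatives were fixed before the data were examined, except where a test or gene is stated to have been chosen later.

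Fold changes were printed from the fitted model where each group held more than 3 counts. Where a group had no counts, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts it is a ratio with a 95% counting interval. These bounds and intervals cover counting error alone and not the spread between libraries. The named genes were the copies of chordin and pinhead, up to 10 genes per direction with the largest fold change at a mean of at least 5 CPM for comparisons with control and for the interaction, up to 5 per direction for the others, and up to 4 members per gene list. Genes of largest change had to be called, to have a gene symbol and, between groups, to have no overlap of library levels. List members were those with the smallest adjusted p in the comparison, so they are not typical members.

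The 24 lists covered notochord, Spemann organizer and prechordal mesoderm, pan-mesoderm, paraxial mesoderm and somite, skeletal muscle, ventral, lateral and posterior mesoderm, targets of the BMP, FGF/ERK and Wnt pathways, Nodal and endoderm, pan-neural, anterior neural and eye field, cement gland, posterior neural and hindbrain, floor plate and hedgehog, neural crest, placode, epidermis, multiciliated cells and ionocytes, blood and endothelium, heart and pronephros, hox genes, ribosomal proteins and stress response. They were written from textbook embryology, some genes stand in more than 1 list, and the chordin and pinhead genes were left out of all. For each list and comparison, members called up and down were counted with p-values adjusted over all genes and over the list alone. Lists were tested with camera in limma, with the preset correlation between genes of 0.01 and again with an estimated correlation, and with fry, each adjusted by Benjamini-Hochberg over the 24 lists of a comparison. Of these list tests, only the camera results are given below. As an analysis added later, genes called higher in both than in each of the other 3 groups were counted, and their overlap with the lists was tested by a one-sided Fisher's exact test.

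The same code was tested on simulated data with the control means in all 8 libraries, trended dispersions and the library sizes. In these data 200 genes, drawn from those with a control mean of about 2 CPM or more, were changed in the Pinhead group alone. The simulated data held no Chordin effect and the same dispersion in every group. The numbers recovered therefore do not cover the unequal spread between libraries of the real groups, or genes scarcely detected in control. For Pinhead against control edgeR called 156 of the 200 (16 of 50 at 1.5-fold, 41 of 50 at 2-fold, 49 of 50 at 4-fold and 50 of 50 at 8-fold) and 9 unchanged genes, and for the interaction 135 of the 200 (7, 30, 48 and 50 of 50) and 7 unchanged genes. DESeq2 1.42.0 called 154 and 126 of the 200.

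Alternatives tried were scaling by relative log expression or the upper quartile, DESeq2 in place of edgeR, no filter on low counts, a filter of 5 CPM in 2 libraries, only the groups compared in the fit, an adjusted p under 0.01, an absolute log2 fold change of at least 1, long and short copies summed, and leaving out each library in turn, where the lone library of a group is taken to vary like the others. For the interaction, a filter of at least 10 counts in every group was added later, as were the counts of list members without single libraries.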

Results

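RNA was sequenced from ectodermal explants of Xenopus laevis, a frog whose isolated embryonic ectoderm forms epidermis when cultured alone and other tissues when it is exposed to signals. The explants were wild type, were kept in culture, and were collected at the early neurula stage. They fell into 4 groups of 2 libraries: control explants (libraries 1 and 2), explants expressing Chordin (3 and 4), explants expressing Flag-tagged Pinhead (5 and 6) and explants expressing both (7 and 8). Chordin is a secreted antagonist of bone morphogenetic proteins (BMPs), and Pinhead is a secreted protein of the early embryo. The series asks about the induction of dorsal mesodermal genes by the pair. Total counts per library were 17455372 and 16049183 in control, 17624840 and 17475416 with Chordin, 19677493 and 15052017 with Pinhead, and 15354108 and 16990883 with both. Xenopus laevis carries a long and a short copy (.L and .S) of many genes, and each copy was counted as a gene of its own. The labels do not say that the libraries of a group came from separate embryo batches, so the p-values measure only the spread between these libraries, which may be technical.

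Each expressed gene was high in the libraries whose labels name it. The chordin copy chrd.S had 816 and 794 CPM (counts scaled to library size) with Chordin and 793 and 934 CPM with both, against 0.483 and 0.656 CPM in control and 0.633 and 1.17 CPM with Pinhead. The pinhead copy pnhd.L had 1250 and 739 CPM with Pinhead and 429 and 486 CPM with both, against 1.21 and 0.328 CPM in control and 1.83 and 2.89 CPM with Chordin. Chordin raised pnhd.L over control by 1.58 ± 0.55 on the log2 scale (adjusted p = 0.0299, 2.83 without library 1), a call lost without library 2 (0.97, adjusted p = 0.165) or 4 (1.24, adjusted p = 0.143). The pnhd.L level with both was lower than with Pinhead alone by a log2 fold change of -1.12 ± 0.26 (SE; edgeR adjusted p = 0.00473), whereas chrd.S was not called different between both and Chordin (0.10 ± 0.13, adjusted p = 0.682). The other chordin copies were low: chrd.1.L had 2.33 and 3.28 CPM with Chordin and 16.8 and 37.6 CPM with both, and chrd.2.L had 2.21 and 2.13 CPM and 16.9 and 39 CPM. Both rose in explants with both proteins over Chordin, by 3.28 ± 0.39 and 3.69 ± 0.40 (adjusted p = 0.0011 and 0.0011), or by 2.58 and 2.96 without library 8. Reads of near-identical gene copies can be exchanged in counting, so levels of single chordin copies are uncertain.

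**Figure D1:**
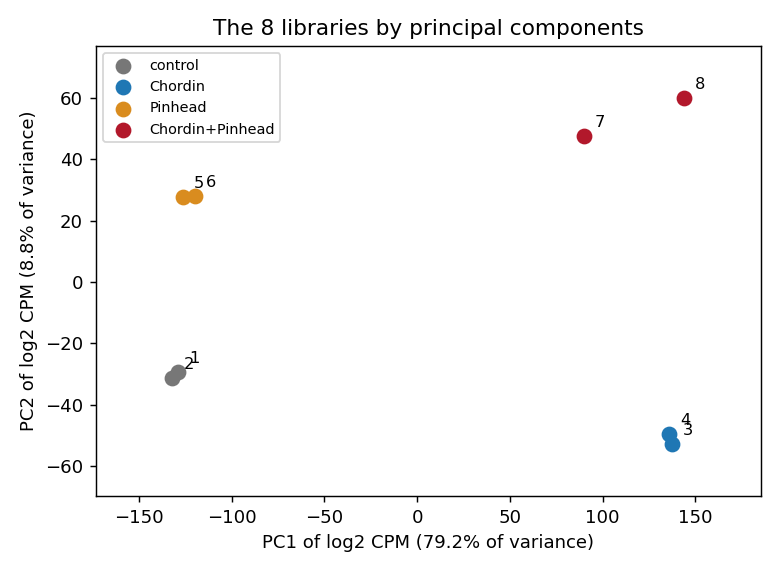
The 8 libraries on the first 2 principal components of log2 CPM, coloured by group and numbered by library. The horizontal axis holds 79.2% of the variance and the vertical axis 8.8%; libraries with Chordin lie to the right, and library 7 lies apart from library 8.

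Expression of Chordin was the main axis of difference among the libraries. The first principal component held 79.2% of the variance and put the 4 libraries without Chordin between -132 and -119.6 and the 4 with Chordin between 89.9 and 143.8. The second held 8.8% and put both groups with Pinhead above both groups without it. Replicate libraries correlated across genes at r = 0.9895 in control, 0.9899 with Chordin, 0.9862 with Pinhead and 0.9665 with both. In the last group library 7 stood at 89.9 on the first component and library 8 at 143.8, and 2 transcripts abundant in control differed between them: has1.S, a hyaluronan synthase of the epidermis list, had 613 CPM in library 7 and 425 CPM in library 8, and tekt1.S, a structural gene of cilia, had 3.8 and 0 CPM.

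Chordin alone turned explants with an epidermal profile into explants with an anterior neural profile. Of 56 tested genes of the anterior neural and eye field list, 45 rose and 3 fell (1 without library 3), and 12 of 13 cement gland genes rose, the cement gland being the mucus organ at the front of the tadpole head. The eye field gene rax.L, a homeobox regulator of eye formation, went from 0.315 ± 0.0186 CPM in control to 854 ± 58.5 CPM with Chordin (SD, n = 2), a 2650-fold rise. The eye gene pax6.L rose 167-fold, the forebrain and eye gene lhx2.L 941-fold, six6.L at least 1370-fold against a floor of 3 counts over the control group, and the cement gland gene ag1.L 37.1-fold. Pan-neural genes rose more often than they fell (36 up and 13 down of 68), among them the RNA-binding protein gene msi1.L (49.2-fold), the neural adhesion gene ncam1.L (40.1-fold) and N-cadherin, cdh2.L (68.1-fold). Of 36 genes of the Spemann organizer and prechordal mesoderm, 16 rose and 6 fell, among them otx2.S (19.6-fold) and hesx1.L (99.1-fold), which are also forebrain genes. Camera, a test of a list against all other genes, called these lists higher (adjusted p = 3.43e-52 for anterior neural, 7.32e-26 for cement gland, 7.44e-10 for pan-neural and 2.12e-07 for organizer). With an estimated correlation between genes the anterior neural and cement gland calls held (adjusted p = 0.0209 and 0.0448) and the pan-neural and organizer calls did not (adjusted p = 0.544 for both). Adjusted over the list alone, 47 anterior neural, 12 cement gland, 37 pan-neural and 16 organizer genes rose.

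Epidermal, ciliated and BMP-dependent transcripts fell with Chordin. Of 66 epidermis genes 56 fell and 5 rose, of 42 genes of multiciliated cells and ionocytes 39 fell and 1 rose, and of 46 BMP pathway targets 40 fell and 5 rose. The epidermal has1.S went from 4650 ± 261 to 270 ± 10.9 CPM, a 17.3-fold fall, while the simple-epithelium keratin krt18.S of the same list rose 18.2-fold. The ionocyte gene ca2.L fell at least 1270-fold, the cilium gene tekt1.S at least 362-fold and the tight junction gene cldn1.L at least 596-fold. BMP ligand genes fell too, bmp4.S 7.14-fold and bmp7.2.L 56.9-fold, as did the BMP target id2.L (5.89-fold), while hes1.S of that list rose 18.7-fold. Ventral, lateral and posterior mesoderm genes fell in 20 of 33 cases and rose in 2 (1 without library 1), and the ventral homeobox gene ventx1.2.S was at least 112-fold lower. Of 54 hox genes, which mark trunk and hindbrain levels, 18 fell, among them hoxa3.S (at least 109-fold), and 2 rose (1 without library 1, 2, 4, 5 or 6). Camera called the falls of epidermis, ciliated cell, BMP target, ventral mesoderm and hox lists (adjusted p = 4.06e-08, 2.06e-14, 1.03e-07, 0.000279 and 0.0181). None of these 5 calls held with an estimated correlation (adjusted p = 0.645, 0.544, 0.645, 0.382 and 0.796), and the hox call was lost without library 8 (adjusted p = 0.0607; 0.0107 to 0.0607 over all alternatives). With p-values adjusted over the list alone, 56, 39, 41, 20 and 16 of their members fell. FGF/ERK targets rose in 26 of 44 cases and fell in 7, with 4.42-fold more etv1.L (camera adjusted p = 0.0011, or 0.665 with an estimated correlation). The FGF/ERK falls numbered 4 without library 1, 3 or 4. Over all 23130 genes tested, 7329 rose and 7408 fell with Chordin (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 3723 and 4839 did so at least 2-fold.

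Pinhead alone raised mesodermal and posterior genes. Of 33 pan-mesodermal genes 21 rose, of 33 ventral, lateral and posterior mesoderm genes 22 rose (13 without library 2), and of 40 paraxial mesoderm genes 19 rose (12 without library 1). The brachyury copy t.S, a T-box regulator of mesoderm, went from 0.665 ± 0.173 to 57.4 ± 20.7 CPM (SD, n = 2), an 85.7-fold rise, and t.L reached 50.5 and 70.2 CPM from 0.0603 and 0 CPM. The T-box gene vegt.S rose 82.9-fold, the posterior homeobox gene evx1.L 60.9-fold, and the caudal-type gene cdx4.L 123-fold (log2 fold change 6.94 ± 0.72, or 7.87 without library 1). The retinoic acid hydroxylase gene cyp26a1.S rose 23.5-fold and the hairy/Enhancer of split type gene esr-5.L 157-fold. Of 54 hox genes 42 rose (19, 18 and 27 without libraries 1, 2 and 5), with hoxb7.L at least 162-fold and hoxd3.L at least 128-fold higher than in control, and of 60 posterior neural and hindbrain genes 40 rose and 4 fell (0, 1 and 1 without libraries 1, 2 and 5). Targets of FGF/ERK and Wnt signalling rose as well, 24 of 44 and 22 of 34 (2 FGF/ERK targets fell, and 0 without any 1 of libraries 1 to 5), including the FGF pathway genes flrt3.S (36.7-fold) and etv1.S (3.24-fold) and the Wnt target sp5l.L (45.7-fold). Notochord genes were called higher in 4 of 30 cases (2 without library 1), including t.L and t.S, and muscle genes higher in 4 and lower in 3 of 39. The muscle calls were few and moved with single libraries: 1, 1 and 2 genes were higher and 1, 0 and 0 lower without libraries 1, 2 and 5, and 7 were higher without library 7 or 8.

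Camera called the rises of the pan-mesoderm, ventral and posterior mesoderm, paraxial mesoderm, hox, posterior neural, FGF/ERK and Wnt lists with Pinhead (adjusted p = 4.26e-45, 7.92e-31, 5.25e-21, 2.64e-48, 2.6e-40, 3.12e-32 and 2.14e-40). With an estimated correlation the ventral and posterior mesoderm and the Wnt lists kept their call (adjusted p = 0.0131 for both), and the pan-mesoderm, paraxial, hox, posterior neural and FGF/ERK lists did not (adjusted p = 0.0763, 0.082, 0.0843, 0.0763 and 0.0763). Adjusted over the list alone, 27 pan-mesoderm, 24 ventral and posterior mesoderm, 24 paraxial, 49 hox, 44 posterior neural, 29 FGF/ERK and 28 Wnt genes rose.

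Some placodal genes fell with Pinhead, and anterior neural genes went both ways. Of 56 anterior neural genes 10 fell and 5 rose, with pax6.L 4.83-fold and otx2.L 3.85-fold lower and the forebrain genes emx2.L and emx2.S 24-fold and 22.4-fold higher, and of 43 placode genes 12 fell, with foxi4.2.S 2.96-fold and isl1.L 1.97-fold lower. The pax6.L fall was between low levels, from 33 counts over the control libraries to 7 over the Pinhead libraries. The anterior falls numbered 3, 3 and 4 without libraries 1, 2 and 5, and the placode falls 7 without library 1. Camera called the placode list lower (adjusted p = 2.79e-06, or 0.387 with an estimated correlation) and did not call the anterior neural list (adjusted p = 0.149). In epidermis 11 of 66 genes fell and 2 rose, and in BMP targets 8 of 46 fell and 7 rose. Camera called the epidermis list lower (adjusted p = 0.00631, or 0.677 with an estimated correlation) and did not call the BMP target list (adjusted p = 0.622). The epidermal falls ranged from 2 without library 1 or 2, through 4 without 3, 4 or 5, to 27 without 7 or 8, and the rises numbered 0 without 2, 1 without 1, 3, 4 or 5 and 7 without 7 or 8. The BMP target falls numbered 3 without 1, 2 or 5, 5 without 3 or 4 and 21 without 7 or 8, and their rises 4 without 1 or 6 and 2 without 2.

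Over all genes tested, Pinhead raised 1562 and lowered 907, 698 and 225 of them at least 2-fold (edgeR adjusted p under 0.05). This count rested on the libraries used. Without control library 1 or 2 it was 471 or 491 higher and 89 or 130 lower, without Pinhead library 5 it was 722 and 212, and without Chordin library 3 or 4 it was 965 or 967 and 377 or 379. Without library 7 or 8, whose spread enters the shared estimate, it was 2576 or 2577 higher and 1911 lower in either case.

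**Figure D2:**
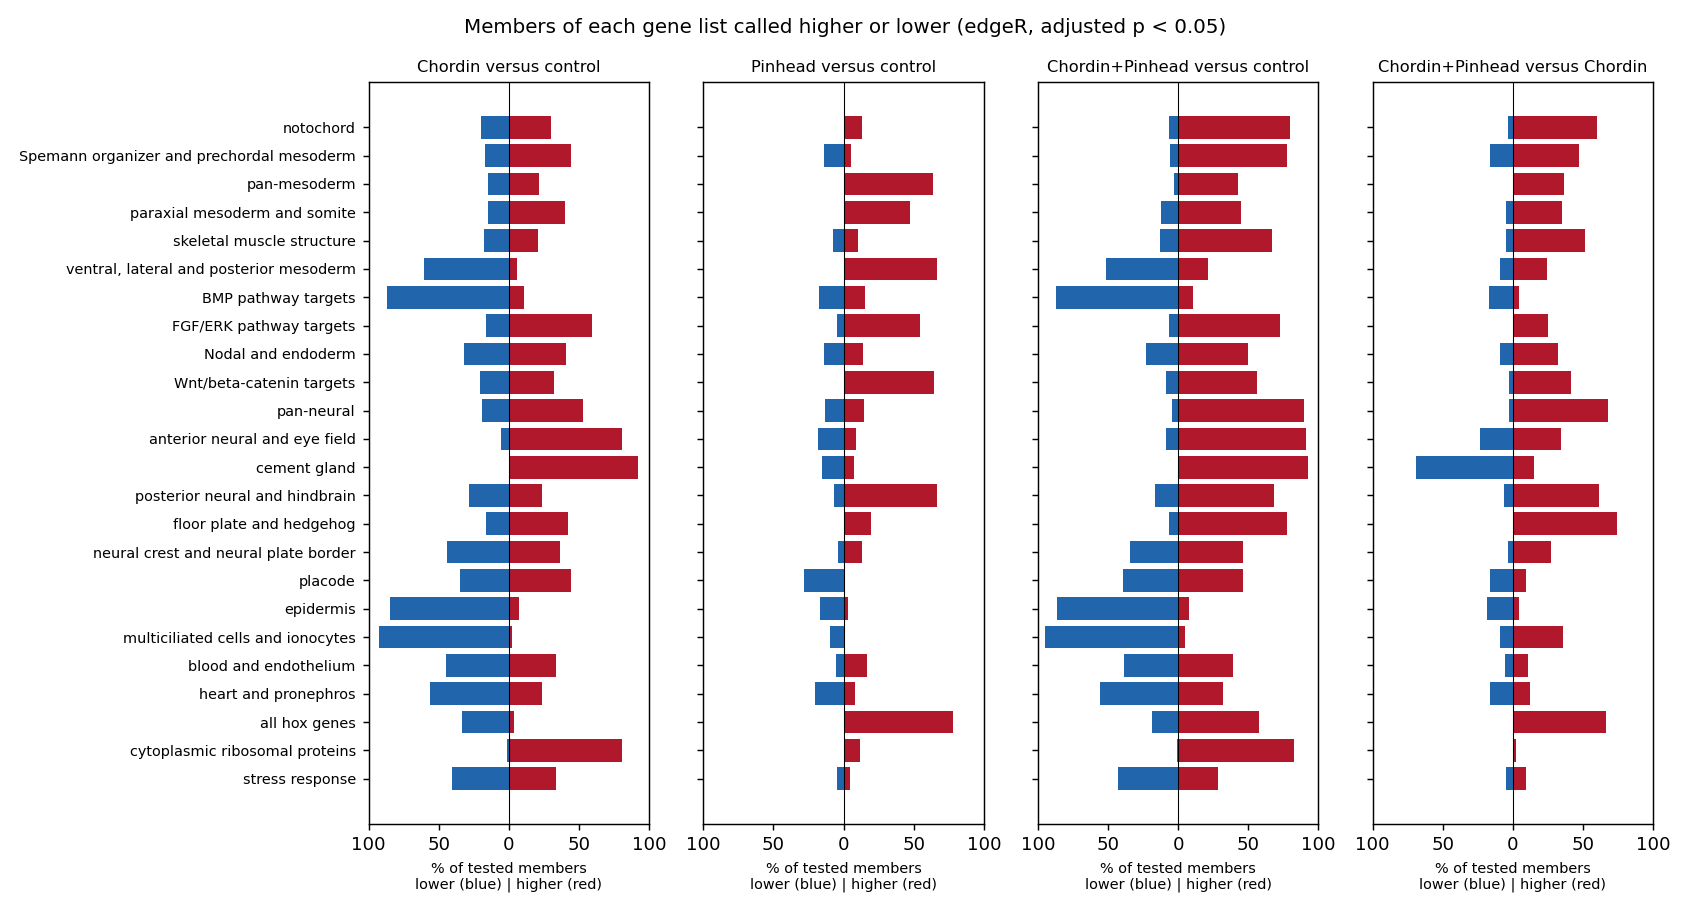
Percentage of tested members of the 24 gene lists called higher (red, right) or lower (blue, left) in 4 comparisons by edgeR at an adjusted p under 0.05. With Chordin 45 of 56 anterior neural genes were higher, with Pinhead 42 of 54 hox genes were higher, and with both over Chordin 18 of 30 notochord genes were higher.

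Explants with both proteins carried neural, notochord, muscle and floor plate transcripts compared with control. Of 30 notochord genes 24 rose and 2 fell, of 36 organizer genes 28 rose and 2 fell (1 without library 1 or 2), of 39 skeletal muscle genes 26 rose and 5 fell, and of 31 genes of the floor plate and hedgehog pathway 24 rose and 2 fell (1 without library 2, 7 or 8). The notochord homeobox gene not.L went from 0.534 ± 0.0129 to 10.7 ± 0.352 CPM (SD, n = 2), a 19.8-fold rise, and the hedgehog target gene ptch1.L rose 18.3-fold. The muscle actin gene actc1.L rose by 7.04 ± 0.75 (log2 fold change and SE), from 0.129 ± 0.0965 to 17.5 ± 10.1 CPM, and by 6.43, 8.02 and 6.31 without libraries 1, 2 and 8. Pan-neural genes rose in 61 of 68 cases and fell in 3 (1 without library 2, 3 or 4), and anterior neural genes rose in 51 of 56 and fell in 5, with msi1.L 59.6-fold, ncam1.L 42.1-fold and pax6.L 187-fold higher. Of the 13 cement gland genes 12 rose. The hindbrain gene cyp26c1.L stood at 138 and 170 CPM against 0.0603 and 0.0656 CPM in control, a ratio of 2460 with a 95% counting interval of 680 to 20300, and the neural gene foxb1.S was at least 311-fold higher. Hox genes were higher in 31 and lower in 10 of 54 cases, and posterior neural genes higher in 41 and lower in 10 of 60. Epidermis genes fell in 57 of 66 cases and rose in 5 (3 without library 2), ciliated cell and ionocyte genes fell in 40 of 42 and rose in 2 (1 without library 1 or 7), and BMP targets fell in 40 of 46 and rose in 5. Here has1.S fell 8.96-fold, bmp4.S 8.94-fold, foxj1.L, the master gene of motile cilia, 5.88-fold, and ventx1.1.S at least 50.1-fold.

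Camera called the notochord, organizer, muscle, floor plate, pan-neural, anterior neural, cement gland and posterior neural lists higher with both than in control (adjusted p = 9.8e-05, 1.16e-12, 0.0021, 2.37e-08, 1.19e-28, 1.22e-61, 3.54e-22 and 9.8e-05), and the epidermis, ciliated cell and BMP target lists lower (2.75e-11, 7.58e-12 and 4.01e-10). Of these 11, only the anterior neural list kept its call with an estimated correlation (adjusted p = 0.0144). The notochord and muscle lists had adjusted p = 0.437, the organizer list 0.335, the pan-neural list 0.27, the cement gland list 0.0544, the posterior neural list 0.455, and the floor plate, epidermis, ciliated cell and BMP target lists 0.347. The hox list, whose members went both ways, was not called (adjusted p = 0.193). When adjusted over the list alone, 25 notochord, 29 organizer, 26 muscle and 24 floor plate genes rose. Pan-mesoderm genes rose in 14 and fell in 1 of 33 cases and paraxial genes rose in 18 and fell in 5 of 40, the rises numbering 22 and 29 without library 7 and the pan-mesoderm falls 3 without library 8 (camera adjusted p = 0.0211 and 0.000666; 0.599 and 0.437 with an estimated correlation). The pan-mesoderm call was lost without library 8 (adjusted p = 0.0856; 0.00029 to 0.0856 over all alternatives). FGF/ERK targets rose in 32 of 44 cases, with 66.3-fold more fgf8.L, and Wnt targets in 19 of 34, with 63.5-fold more sp5l.L (camera adjusted p = 9.49e-07 and 0.000729, both 0.347 with an estimated correlation). Over all genes tested 7691 rose and 7427 fell, 3996 and 4958 of them at least 2-fold.

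**Figure D3:**
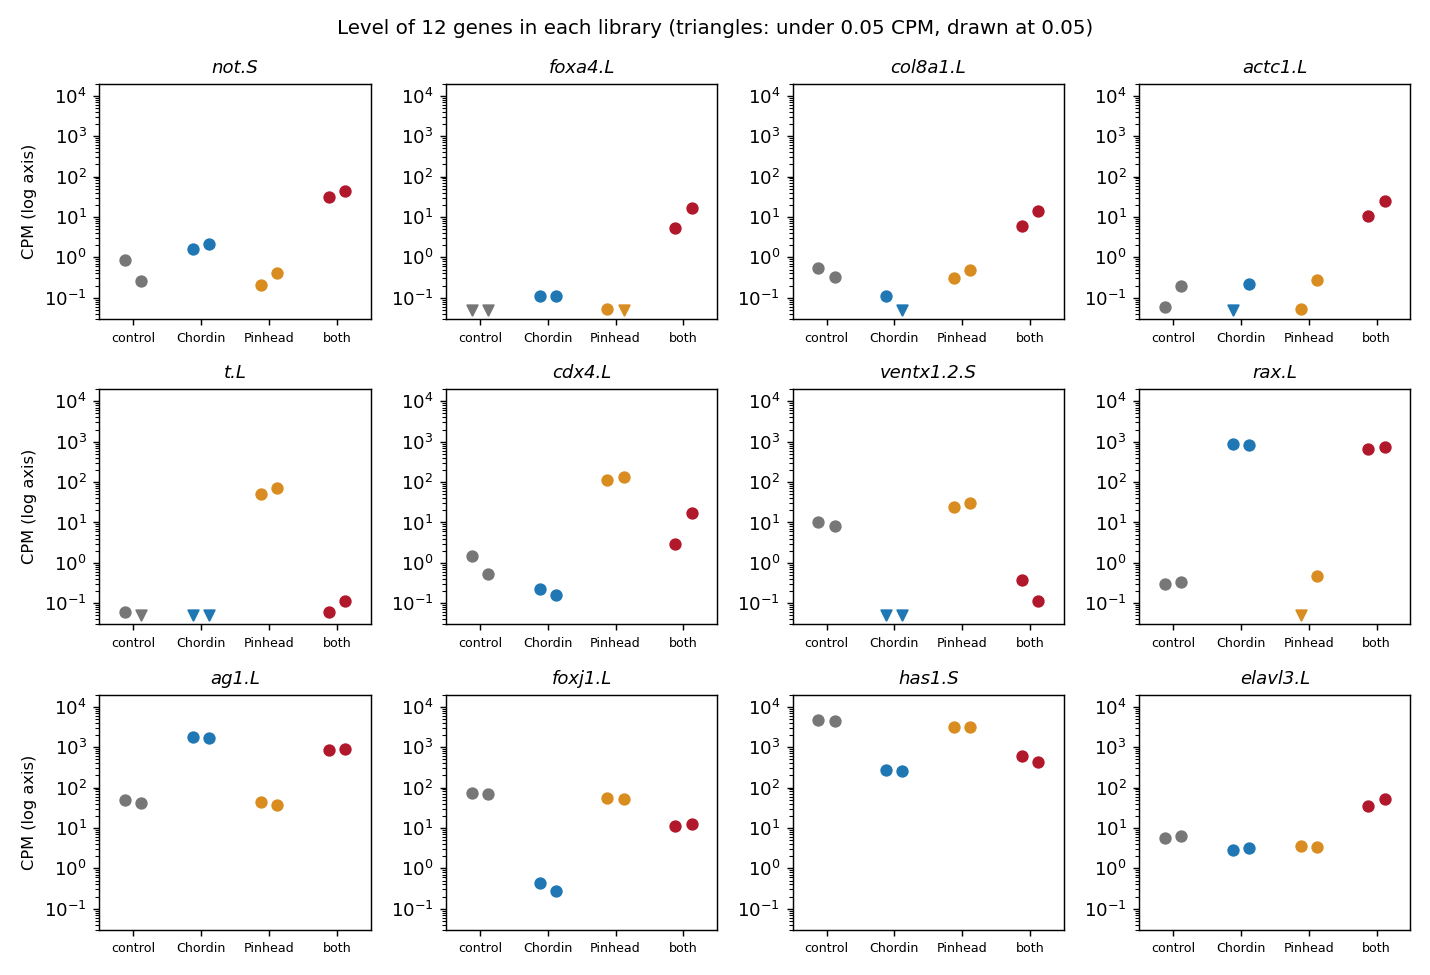
Level of 12 genes in each of the 8 libraries, in CPM on a log axis, with 1 point per library; values under 0.05 CPM are drawn as triangles at 0.05. The genes not.S and foxa4.L were highest in both libraries with Chordin and Pinhead together, and t.L was highest in the libraries with Pinhead alone.

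Added to Chordin, Pinhead raised mesoderm genes, dorsal ones among them, which is the comparison closest to the question of the series. Of 30 notochord genes 18 rose and 1 fell, of 36 organizer and prechordal genes 17 rose and 6 fell, and of 39 skeletal muscle genes 20 rose and 2 fell. The notochord homeobox gene not.S went from 1.87 ± 0.371 CPM with Chordin to 37.1 ± 9.31 CPM with both (SD, n = 2), a 19.8-fold rise with adjusted p = 6.26e-05, higher in both libraries than in any other. The notochord collagen col2a1.L rose by 4.05 ± 0.45 on the log2 scale (4.69 and 3.41 without libraries 4 and 8), and the forkhead gene foxa4.L of the organizer and notochord by 6.58 ± 0.79 (5.55 without library 8). The calcium pump gene atp2a1.L of muscle was at least 144-fold higher, and muscle actin actc1.S rose by 6.26 ± 0.58 (5.4 without library 8). The organizer-expressed kinase gene pkdcc.1.S rose 2.89-fold. Among genes chosen after their values were seen, the organizer ligand admp.L had 7.91 and 23.7 CPM with both and 0 in the other 6 libraries, the notochord and floor plate signal shh.L had 5.3 and 17.7 CPM with both and 0 in both Chordin libraries, and the organizer gene gsc.L had 3.99 and 7.38 CPM against 2.6 and 0.765 CPM with Chordin and was not called (adjusted p = 0.0951). The notochord gene col2a1.L was lower in library 7 than in library 8 (8.47 and 18 CPM), while not.L was alike in them (10.5 and 11 CPM). Camera called the notochord, organizer and muscle lists higher with both than with Chordin (adjusted p = 5.66e-20, 6.29e-07 and 3.38e-12), and no such call held with an estimated correlation (adjusted p = 0.149, 0.214 and 0.194). Adjusted over the list alone, 22 notochord, 20 organizer and 21 muscle genes rose. Leaving out Chordin library 3 or 4 left 11 or 10 notochord, 5 organizer and 7 muscle genes higher and 0 or 1 organizer, 0 notochord and 0 or 1 muscle genes lower (1 muscle gene without library 5 or 6), while without library 7 20, 20 and 23 were higher.

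Neural tube and posterior genes rose in the same comparison. Of 31 floor plate and hedgehog genes 23 rose, of 68 pan-neural genes 46 rose and 2 fell (1 without any 1 of libraries 1 to 4), of 60 posterior neural genes 37 rose and 4 fell, and of 54 hox genes 36 rose. The ventral neural tube genes arx.L and nkx6-2.L rose 11.4-fold and 25.5-fold, the neuronal RNA-binding protein gene elavl3.L 14.4-fold, and hoxa3.S at least 30.4-fold. Pan-mesoderm genes rose in 12 of 33 cases, with wnt11b.L higher by 3.62 ± 0.32 on the log2 scale. FGF/ERK targets rose in 11 of 44, with flrt3.S 3.3-fold higher, and Wnt targets in 14 of 34, with sp5l.L 8.69-fold higher. Ventral, lateral and posterior mesoderm genes rose in 8 and fell in 3 of 33 cases, with a median log2 fold change of 1.91 over the list (1.03 with members at or under 3 counts in a group set to their bound). Camera called this list higher (adjusted p = 0.00781, or 0.196 with an estimated correlation), and without libraries 3 and 4 its rises numbered 1 and 0 and its falls 0 and 1, with 7 falls without library 7. Genes of the most anterior territories moved down or both ways: 9 of 13 cement gland genes fell and 2 rose, with ag1.L 1.99-fold lower, and 13 of 56 anterior neural genes fell while 19 rose. The retinal gene vsx1.L fell 11.7-fold and the eye gene mab21l1.L 9.8-fold. Of 42 ciliated cell and ionocyte genes 15 rose and 4 fell. The cilium gene foxj1.L rose 32.8-fold, while foxn4.L fell 2.9-fold. By camera the floor plate, pan-neural, posterior neural, hox and pan-mesoderm lists were higher (adjusted p = 8.28e-33, 1.66e-44, 2.07e-22, 1.94e-27 and 9.54e-11), as were the FGF/ERK, Wnt, anterior neural and ciliated cell lists (3.06e-05, 6.72e-11, 0.00125 and 2.92e-06), and the cement gland list was lower (0.000369). None of these 10 calls held with an estimated correlation (adjusted p = 0.138 for floor plate, pan-neural and Wnt, 0.194 for posterior neural, 0.214 for pan-mesoderm, 0.196 for hox, anterior neural and cement gland, 0.314 for FGF/ERK and 0.442 for ciliated cells), and the ciliated cell call was lost without library 7 (adjusted p = 0.0657; 2.66e-54 to 0.0657 over all alternatives). With p-values adjusted over the list alone, 25 floor plate, 53 pan-neural, 46 posterior neural, 47 hox and 19 pan-mesoderm genes rose. Without Chordin library 3 or 4 the rises numbered 11 or 12 for floor plate, 27 or 23 for pan-neural, 12 or 13 for posterior neural, 10 or 11 for hox, 3 for pan-mesoderm, 4 for FGF/ERK, 8 or 9 for Wnt, 10 or 12 for anterior neural, 1 for cement gland and 3 or 2 for ciliated cells. The falls then numbered 2 or 4 for cement gland and 5 or 6 for anterior neural. Pan-mesoderm rises numbered 22 without library 7 and 7 without library 1 or 2. Ciliated cell rises numbered 31 without library 8, 8 without 1 or 2 and 9 without 5 or 6, and ciliated cell falls 9 without library 7.

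Over all genes tested, 1494 were higher and 982 lower with both than with Chordin, 1008 and 259 of them at least 2-fold. The higher genes numbered 472 or 474 without Chordin library 3 or 4. The lower genes numbered 182 or 174 without those, 611 or 623 without control library 1 or 2, and 2179 without library 7, where rises made up 44% of calls in place of 60.3%. Epidermis and BMP target lists moved with library 7: with all libraries 12 of 66 epidermis genes were lower and 3 higher, 37 were lower without library 7, 13 were higher without library 8, and 3 were lower and 1 higher without library 3 or 4. Of 46 BMP targets 8 were lower and 2 higher; 24 were lower without library 7, 5 without 1 or 2, 0 without 3 and 2 without 4, and 9 were higher without library 8 and 1 without any 1 of libraries 1 to 6. Camera called both lists lower with all libraries (adjusted p = 0.00524 and 0.0306; 0.651 and 0.684 with an estimated correlation). Without library 8 both turned to higher, short of a call (adjusted p = 0.156 and 0.09), and the BMP target call was lost without library 3 (adjusted p = 0.265).

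Added to Pinhead, Chordin lowered ventral and posterior mesoderm genes and raised notochord and head genes. Of 33 ventral, lateral and posterior mesoderm genes 30 fell, with a median log2 fold change of -3.58 over the list (-3.58 with members at or under 3 counts in a group set to their bound), and of 33 pan-mesoderm genes 18 fell and 6 rose. The brachyury copy t.S went from 57.4 ± 20.7 CPM with Pinhead to 2.57 ± 2.22 CPM with both, a log2 fold change of -4.44 ± 0.45 (-3.81 and -5.81 without libraries 7 and 8), and t.L fell from 50.5 and 70.2 to 0.0623 and 0.112 CPM. The ventral homeobox genes ventx1.1.S and ventx3.2.L were at least 194-fold and 249-fold lower. Hox genes fell in 37 of 54 cases, with log2 fold changes of -3.60 ± 0.18 for hoxa3.S and -4.72 ± 0.29 for hoxc5.S. Notochord genes rose in 22 and fell in 4 of 30 cases, not.S by 121-fold, organizer genes rose in 28 and fell in 4 of 36 (2 without library 6), and muscle genes rose in 24 and fell in 5 of 39. Anterior neural genes rose in 49 of 56 cases, with fezf2.L at least 989-fold higher, pan-neural genes in 57 of 68, with sox11.S 29-fold higher, and cement gland genes in 12 of 13. BMP targets fell in 41 of 46 cases, epidermis genes in 56 of 66 and ciliated cell genes in 40 of 42.

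Camera called the falls of the ventral mesoderm, pan-mesoderm, hox, BMP target, epidermis and ciliated cell lists (adjusted p = 5.33e-13, 0.00305, 4.82e-06, 1.54e-10, 2.55e-09 and 5.16e-11) and the rises of the notochord, organizer, muscle, anterior neural, pan-neural and cement gland lists (0.000874, 6.12e-15, 0.00405, 1.46e-69, 1.11e-31 and 1.36e-26). With an estimated correlation the anterior neural and cement gland calls held (adjusted p = 0.0377 each). The others did not: adjusted p = 0.0944 for ventral mesoderm, 0.61 for pan-mesoderm, 0.506 for hox, notochord and muscle, 0.222 for organizer, 0.199 for pan-neural, and 0.451 for BMP targets, epidermis and ciliated cells. Adjusted over the list alone, 31 ventral mesoderm, 19 pan-mesoderm and 37 hox genes fell. Over all genes tested 7102 rose and 7165 fell, 3416 and 4850 of them at least 2-fold.

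The single proteins also differed from each other when compared directly. All 33 tested ventral, lateral and posterior mesoderm genes were higher with Pinhead than with Chordin, as were 53 of 54 hox genes and 24 of 33 pan-mesoderm genes (4 lower). The numbers without single libraries were 30 to 33 for ventral mesoderm. The T-box genes t.L and vegt.S were at least 716-fold and 504-fold higher with Pinhead. Anterior neural genes were lower with Pinhead in 45 of 56 cases and higher in 4, with pax6.L 809-fold lower, cement gland genes lower in 11 of 13, with ag1.L 43.4-fold lower, and pan-neural genes lower in 36 and higher in 13 of 68, with msi1.L 42.8-fold lower. Epidermis genes were higher in 52 of 66 cases, with has1.S 11.6-fold higher, ciliated cell genes in 38 of 42 and BMP targets in 40 of 46, with bmp7.2.L 28.1-fold higher. Camera called all 9 lists (adjusted p = 1.98e-14, 1.49e-14, 9.36e-07, 1.46e-58, 3.13e-30, 5.16e-11, 2.07e-06, 7.68e-14 and 5.49e-08 in the order given). With an estimated correlation the ventral mesoderm, anterior neural and cement gland calls held (adjusted p = 0.0395, 0.0338 and 0.0338) and the hox, pan-mesoderm, pan-neural, epidermis, ciliated cell and BMP target calls did not (0.432, 0.447, 0.432, 0.544, 0.435 and 0.447). Over all genes tested 7205 were higher and 6823 lower with Pinhead than with Chordin, 4694 and 3170 of them at least 2-fold.

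The effect of Pinhead differed with and without Chordin for part of the genes. The interaction is the change from Chordin to both minus the change from control to Pinhead on the log2 scale. It was positive for notochord genes in 10 of 30 cases, and for pan-neural genes positive in 25 and negative in 5 of 68. The notochord gene not.L had an interaction of 4.82 ± 0.60 (5.5 without library 4; adjusted p = 0.00217), and not.S one of 5.21 ± 0.81, which lost its call without control library 1 (4.11, adjusted p = 0.108). The neuronal gene elavl3.L had 4.64 ± 0.33, the organizer kinase gene pkdcc.1.S 2.54 ± 0.20 and the cilium gene foxj1.L 5.43 ± 0.24. Organizer genes were positive in 6 of 36 cases, floor plate genes in 6 of 31, and ciliated cell genes positive in 16 and negative in 3 of 42. Camera called the notochord, organizer, pan-neural, floor plate and ciliated cell lists positive (adjusted p = 3.98e-06, 0.00504, 2.4e-11, 0.0044 and 6.86e-08). None of these held with an estimated correlation (adjusted p = 0.72 for notochord and pan-neural and 0.783 for organizer, floor plate and ciliated cells), and the floor plate call was lost without library 8 (adjusted p = 0.0673; 0.000327 to 0.0673 over all alternatives). When adjusted over the list alone, 10 notochord and 32 pan-neural interactions were positive. The positive notochord interactions numbered 3, 5, 5, 4, 5 and 6 without libraries 1 to 6 in turn. The pan-neural numbers were 12, 16, 16 and 12 positive and 3, 2, 2 and 3 negative without libraries 1 to 4. Floor plate interactions were positive in 2 cases without library 1, 3 without any 1 of libraries 2 to 6, 13 without 7 and 10 without 8. Ciliated cell interactions were positive in 6, 7, 4, 3, 9 and 8 cases without libraries 1 to 6 and 30 without library 8, and negative in 9 without library 7.

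On the log2 scale, some signalling targets that rose with Pinhead alone rose less, or were not called higher, when Pinhead was added to Chordin. The pnhd.L level was also lower with both than with Pinhead alone (log2 fold change -1.12 ± 0.26). Its own interaction was -2.71 ± 0.60 (edgeR adjusted p = 0.0237). Smaller rises of targets therefore cannot be told apart from an effect of less pinhead RNA. Interactions were negative for 15 and positive for 3 of 44 FGF/ERK targets, and negative for 9 and positive for 2 of 34 Wnt targets: the ETS factor gene etv1.S, which was not called between Chordin and both (adjusted p = 0.318), had -1.88 ± 0.14, flrt3.L -2.27 ± 0.18 and sp5l.L -2.39 ± 0.34. The retinoic acid binding protein gene crabp2.L, at 1.32 ± 0.0109 CPM in control, 446 ± 4.27 with Chordin, 115 ± 20.7 with Pinhead and 941 ± 28.7 with both, had -5.36 ± 0.20. In CPM it gained more when Pinhead was added to Chordin than with Pinhead alone, so the sign depends on the scale. Ventral mesoderm genes were negative in 5 of 33 cases. Camera called the FGF/ERK and Wnt lists negative (adjusted p = 2.09e-07 and 0.0049), though not with an estimated correlation (adjusted p = 0.72 for both), and did not call the ventral mesoderm list (adjusted p = 0.196). Adjusted over the list alone, 16 FGF/ERK and 10 Wnt interactions were negative. The negative Wnt interactions numbered 3, 4, 3 and 3 without libraries 1 to 4, the positive Wnt ones 0 without 1, 3, 4 or 5 and 1 without 2 or 6, and the positive FGF/ERK ones 0 without 1, 2, 3 or 5, 1 without 4, 6 without 6 and 5 without 8. The negative ventral mesoderm interactions numbered 1 without library 1 or 3, 0 without 2 or 4, 3 without 6, 10 without 7 and 9 without 8.

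Over all genes tested 1213 interactions were positive and 1323 negative, 776 and 647 of them at least 2-fold. The positive ones numbered 317, 396, 302, 254 and 611 without libraries 1 to 5 in turn and 2169 without library 8, and the negative ones 320, 401, 335, 273 and 658 without libraries 1 to 5 and 2805 without library 7. Of the 1213 genes with a positive interaction, 845 were also called lower with Chordin than in control, and of the 1323 with a negative one, 613 were called higher with each protein alone. These calls share libraries with the interaction, so part of the match follows from shared sampling error. Library 7 also held RNA of control-abundant genes near silent with Chordin, at a median of 10.3% of control over 147 genes. That alone can give such genes a positive interaction, so the 845 are not all shown to be effects of Pinhead.

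Dorsal and neural tube genes stood out among transcripts that were highest with both proteins. In a count made after the comparisons were seen, 687 genes were higher with both than in each of the other 3 groups by edgeR at an adjusted p under 0.05, and 528 were lower than in each. The 687 held 15 of 30 notochord genes where 0.891 would be expected by chance (Fisher's exact test, one-sided, adjusted p = 8.72e-15), 15 of 36 organizer genes (1.59e-13), 13 of 39 muscle genes (2e-10), 19 of 31 floor plate genes (9.13e-21) and 38 of 68 pan-neural genes (6.26e-39). They held 18 of 56 anterior neural genes (1.15e-13), 8 of 52 neural crest and plate border genes (0.000473), 6 of 40 paraxial mesoderm genes (0.00327), 4 of 22 Nodal and endoderm genes (0.00981) and 4 of 33 pan-mesoderm genes (0.0382). Genes of a list are not independent of each other, so these Fisher p-values are too small to the extent that they move together. The 687 come from comparisons in which these lists were already counted, so the overlaps add no independent support. They were not tested again without single libraries. Of the 687, 230 also had a positive interaction, 26 of them with 3 or fewer counts in a single-protein group. Without library 3 or 4 the genes higher than in each other group numbered 245 or 234, and those lower 75 or 57; the lower ones numbered 283 or 289 without library 1 or 2, 1527 without library 7 and 339 without library 8.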

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

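All 7 tests of explanations in this part were chosen after the result was seen.

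Library 7 held RNA of control-abundant genes that were near silent in the other libraries with Chordin: over 147 genes with at least 20 CPM in control and under 2% of that in libraries 3, 4 and 8, its median level was 10.3% of control (quartiles 7.7% and 12.8%). If these transcripts came from cells with the mean control profile, all of them should stand near that share. The level expected was this share plus the level in libraries 3, 4 and 8. By a negative binomial test 8 of the 147 genes lay under 0.5 times that level. Of these, 7 lay under 0.5 times the share itself, such as foxi4.2.S at 0.685 CPM where the share gives 6.13. The 5th and 95th percentiles of the 147 genes were 4.16% and 17.9%. Control-like cells of another mix could differ in single genes, so the test cannot set them aside. In CPM, chrd.S and pnhd.L were both lower in library 7 than in library 8. Cells with Pinhead and without Chordin may not be the source. For this, 8 genes had at least 10 CPM with Pinhead and far lower levels in control and in libraries 3, 4 and 8. In library 7 these genes, t.L and vegt.S among them, reached at most 0.63% of their Pinhead level. Notochord genes were lower in library 7 than in library 8 by a median log2 ratio of -1.15 over 18 raised members (upper quartile -0.45). Dilution by other cells at the 10.3% share would give -0.16, but the share of other cells was not measured. An incomplete response to Chordin in library 7 also stays open and was not tested, and no difference named by the design separates the libraries.

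The chordin copies chrd.1.L and chrd.2.L rose when Pinhead was added to Chordin. Reads of the expressed chrd.S assigned to the L copies should hold a fixed share of chrd.S, yet the L copies stood at 0.556% and 0.681% of chrd.S with Chordin alone and at 4.24% and 8.21% with both. Exchange of reads therefore may not account for the rise, and induction of the embryo's own chordin genes by the 2 proteins together is a hypothesis. For the low counts in the libraries with Chordin alone, at most 0.681% of chrd.S, true transcripts and exchanged reads cannot be told apart, since each copy had 39 to 60 counts there.

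Ventral, lateral and posterior mesoderm genes rose with Pinhead and were lower with both proteins than with Pinhead alone. Less pinhead RNA is a candidate explanation, since pnhd.L was lower with both by 1.12 on the log2 scale, but the upper quartile of the 33 genes was -2.33 and their median -3.58. This counts against less pinhead RNA only if targets fall no faster than pnhd.L. Between the 2 Pinhead libraries a difference of 0.76 in log2 pnhd.L went with a median difference of -0.01 over 698 raised genes. Those genes were called by a test on these same libraries, which favours genes alike in them, so this value cannot decide the question. Both of these libraries had more pnhd.L than the libraries with both proteins, so the pair does not cover that lower range. The fall under Chordin without Pinhead had a median of -3.02 over the same list of 33 genes, with no bound set for members with few counts. It lay within the quartiles of the change from Pinhead to both (-4.99 and -2.33), a wide range, so equal effects are not shown. That the same effect of Chordin with and without Pinhead explains their lower level with both is a hypothesis formed from these data.

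The effect of Pinhead on 1213 genes was more positive with Chordin than without it, and on 1323 genes more negative. Of genes raised by Pinhead without Chordin, 264 were raised with it too, where 101 would be expected if the calls were independent, and 90 were lowered with it, where 66 would be. Of genes lowered by Pinhead without Chordin, 80 were lowered with it too, where 39 would be expected, and 107 were raised with it, where 59 would be. Calls in opposite directions also exceeded the expected numbers, so part of each excess may reflect genes that are more readily called in any comparison. The 2 comparisons share no library, though they share the fitted model, and these overlaps were not counted again without single libraries.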

How the results depend on the processing

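Chosen after results were seen were the later filter for the interaction, the counts of genes higher or lower in both than in each other group, and the counts of list members without single libraries. No paired analysis was possible because library numbers are not shared between groups. Other values of a constant added before taking logs were not tried. They would bear on the log2 CPM used for the principal components and the replicate correlations.

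A log2 fold change of at least 1 left 3723 and 4839 genes up and down for Chordin, 698 and 225 for Pinhead, 3996 up for both against control, 259 down for both against Chordin, 3416 up for both against Pinhead, 4694 and 3170 for Pinhead against Chordin, 776 and 647 for the interaction, and 445 higher and 72 lower than in each other group. An adjusted p under 0.01 left 664 and 186 for Pinhead, 772 and 318 for both against Chordin, 315 and 328 for the interaction, and 358 and 131 against each other group. Without a filter the number down with Pinhead was 1651, both against Chordin gave 2483 and 1645, the interaction 2338 and 2157, and 996 were lower than in each other group. With only control and Pinhead in the fit 1619 fell with Pinhead, and with long and short copies summed 448 were higher than in each other group. Under scaling by relative log expression or the upper quartile, DESeq2 and the stricter filter every gene count for the 7 comparisons lay within 1.5 times the reported one, as did the later filter for the interaction (1108 and 1486 of 20116 genes). Upper-quartile scaling moved the median of all genes to 0.117 for both against control and 0.115 for both against Pinhead.

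Leaving out each library in turn gave ranges of 471 to 2577 up and 89 to 1911 down for Pinhead, 472 to 2056 and 174 to 2179 for both against Chordin, 254 to 2169 and 273 to 2805 for the interaction, and 234 to 880 higher and 57 to 1527 lower than in each other group. Camera called 8 to 14 lists for the interaction. Counts for Chordin or both against control, both against Pinhead and Pinhead against Chordin stayed within 1.5 times.

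Of 259 single-gene results checked, 253 were called, and 229 of these stayed called in the same direction under each alternative that gave them a value. The fit of only the groups compared gave values for 217 of the 259, mainly because it has none for the interaction, and the stricter filter for 254. None of the 253 changed sign in the values given. The change of chrd.S from Chordin to both, which was not called, ranged from -0.01 without library 8 to 0.17 without library 7. In list tests, 1 of 96 camera calls was lost under relative log expression (heart and pronephros with Pinhead) and 3 without a filter (placode with Chordin and with both against control, Nodal with both against control). When single libraries were left out, 14 of the 96 calls were lost or turned at least once. Nodal with both against control was lost without each library but 7, with 0.0097 to 0.107 over the libraries left out. Placode was lost with both against control without library 7 (0.351), with 0.00466 to 0.351 over the libraries left out, and with Chordin without 7 (0.554) or 8 (0.274), with 0.00247 to 0.554. BMP targets in both against Chordin turned to higher without library 8 (adjusted p = 0.09), with 2.35e-10 to 0.265 over the libraries left out, and epidermis likewise (adjusted p = 0.156), with 9.62e-14 to 0.156.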

Other observations

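The counts of list members without single libraries and the reading of pnhd.S were chosen after the results were seen.

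Of 52 neural crest and plate border genes, 14 rose and 2 fell when Pinhead was added to Chordin (7 and 4 rose without libraries 3 and 4; camera in limma adjusted p = 0.000369, or 0.196 with an estimated correlation), and 19 rose and 23 fell with Chordin alone (adjusted p = 0.803). Of 22 Nodal and endoderm genes 7 rose when Pinhead was added to Chordin (1 and 2 without libraries 3 and 4; camera adjusted p = 0.0224, 0.442 with an estimated correlation and 0.242 without library 8; 5.17e-05 to 0.242 over all alternatives). Paraxial mesoderm genes rose in 14 of 40 cases in that comparison (4 without library 3 or 4 and 27 without library 7; camera adjusted p = 3.04e-08, or 0.196 with an estimated correlation). Blood and endothelium genes rose in 7 and fell in 7 of 18 cases with both proteins against control (camera adjusted p = 0.803).

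Heart and pronephros genes fell in 14 of 25 cases and rose in 6 with Chordin (camera adjusted p = 0.788), and fell in 5 and rose in 2 with Pinhead. Camera put the list lower with Pinhead (adjusted p = 0.0469, or 0.582 with an estimated correlation), a call lost without library 2 or 5 (adjusted p = 0.0604 and 0.102; 0.000114 to 0.102 over all alternatives). The Pinhead falls numbered 2 without library 1, 2 or 5 and 9 without 7 or 8. Placode genes went both ways with Chordin, 19 up and 15 down of 43 (camera adjusted p = 0.00561, or 0.665 with an estimated correlation), and camera lost its call of a rise without library 7 or 8 (adjusted p = 0.554 and 0.274; 0.00247 to 0.554 over all alternatives).

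Ribosomal protein genes rose slightly with Chordin, 82 of 102 called up (52 without library 2) with a median log2 fold change of 0.38, and 0.37 or 0.45 under the other scalings (camera adjusted p = 0.002, or 0.796 with an estimated correlation). With Pinhead 12 of 102 rose, with a median of 0.18 and counts of 1 without library 1 or 2, 2 without 3 or 4, 5 without 5, 7 without 6 and 25 without 7 or 8. Camera called the list higher with Pinhead (adjusted p = 8.19e-05, or 0.653 with an estimated correlation), but not without library 6 (0.079), with 1.55e-10 to 0.079 over the alternatives. With both against control 84 of 102 rose (48 without library 2; camera adjusted p = 0.00183, or 0.599 with an estimated correlation). Stress response genes rose in 14 and fell in 17 of 42 cases with Chordin (camera adjusted p = 0.39), and in 2 and 2 with Pinhead (adjusted p = 0.29).

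The short pinhead copy pnhd.S, which is not the copy found at high levels, had 7.07 and 9.98 CPM with Pinhead and 0.374 and 0.839 CPM with both. It stood at 0.564% and 1.35% of pnhd.L with Pinhead and at 0.0871% and 0.173% with both, so a fixed share of pnhd.L reads assigned to it would not give all 4 values.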
